A study of Mus musculus with 4 samples.

How the data were processed

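Gene expression was measured by RNA-seq of total RNA from whole mouse kidney in 4 libraries, 2 from mice with autosomal dominant polycystic kidney disease (ADPKD) and 2 from wild-type (WT) mice. The ADPKD mice carried a floxed Pkd1 gene and a tamoxifen-inducible Cre recombinase, per the labels. The labels of all 4 samples, WT included, give tamoxifen at 10 mg/kg on postnatal day 10. RNA was isolated with TRIzol and enriched with oligo dT before adaptor ligation, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The labels do not say that the libraries came from separate animals, so the p-values measure the spread between these samples. ADPKD replicates 1 and 2 had Xist at 0.0180 and 29.6 FPKM and Ddx3y at 15.1 and 0.0482 FPKM. These values argue against technical copies of the same animal in that group. The WT libraries differed by more than counting noise, with a chi-square per gene of 58.6 over 17521 genes. Acsm3 stood at 0.474 and 38.1 FPKM and Hba-a1 at 692 and 151 FPKM in WT replicates 1 and 2, both genes chosen after their values were seen. This argues against technical copies of the same RNA in WT, but does not show that the WT libraries came from separate animals.

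The values analysed were FPKM per gene (reads per kilobase of exon, scaled to the assigned reads of the library), as deposited. Per the submitters' processing notes, Bowtie2 and DESeq2 were used with the mm10 genome build, without their versions or roles. Per the file headers, the deposited table of gene positions and lengths came from featureCounts 1.6.0 with the Ensembl annotation of GRCm38, release 98. Reads in exons were counted per gene name, reads with several alignments were included, and neither a strand nor a paired-end option was set, per the file headers. Genes with near-identical copies, overlapping genes and antisense genes can therefore share or lose reads. Positions in the text are those of the deposited table, on GRCm38. From that table only the positions and the exon length (unit: bases) were used. Its 16 further columns of per-sample values, 8 of counts and 8 without a name, were not used here, because they are named for 8 libraries (4 per group) and could not be matched by name to the 4 samples. By value, the reads recovered from the FPKM of each library equalled 1 of the count columns for 100% of genes, under replicate numbers that mostly differ from those of the samples.

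The FPKM table listed 32176 rows. Names of 25 rows had been turned into calendar dates, and these rows were left out of the tests, which left 32151 genes; they held between 0.118% and 0.151% of the reads of a library. Multiplied by exon length, 100% of the FPKM values of each library were whole multiples of 1 read within a tolerance of 0.01 reads. The depth recovered in this way was 18385710 assigned reads for WT replicate 1, 18001308 for WT replicate 2, 18562606 for ADPKD replicate 1 and 19955120 for ADPKD replicate 2. At that depth 1 read on a gene of 1 kb was worth between 0.0501 and 0.0556 FPKM. A value of 0 allows up to 3 reads, which for a gene of 1 kb is between 0.150 and 0.167 FPKM. Floors and confidence intervals (Wilson, 95%) cover counting error only. Gene types came from GENCODE mouse release M21 (GRCm38), in which 97.5% of the gene names were found.

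Each value was transformed as log2(FPKM + 1), and the 17001 genes with a mean FPKM of at least 0.5 over the 4 libraries were tested. ADPKD was compared with WT by limma 3.58.1 (R 4.3.3) with an intensity trend, a two-sided moderated test with 2 residual degrees of freedom and a prior of 2.55. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p below 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. An exact permutation test of 2 against 2 libraries cannot give a two-sided p below 0.333, so no permutation p was used to call a gene. Gene lists for kidney biology, kidney and other cell types and sample quality, 36 in all, were tested with camera at a preset correlation of 0.01 where at least 5 members were tested, with Benjamini-Hochberg adjustment over the 33 lists tested. Camera compares a list with all other genes; fry, which asks whether the genes of a list move 1 way on balance, and camera with an estimated correlation were run beside it.

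The groups, the tests, the gene lists, the rule for named genes and the other settings listed below were fixed before the data were examined. The rule named Pkd1 and Bcat1, the 6 largest rises and 6 largest falls among called genes whose groups do not overlap and whose mean FPKM is at least 5 (leaving out predicted genes, pseudogenes and immunoglobulin segments), the 2 members with the smallest adjusted p of each biology list and 1 of each cell type list. Other list members are named only as part of a count of 5 or fewer, or are said to have been chosen after their values were seen. A gene that the rule names and some members of small counts are not reported here. The other settings were pseudocounts of 0.1 and 0.5, no filter, a mean FPKM of at least 5, quantile normalization, median-of-ratios scaling, each library left out in turn, the replicate number as a block, limma without the trend and with a robust prior, an adjusted p below 0.10, and an absolute log2 fold change of at least 1. After seeing the data, 3 settings were added: limma-voom on the recovered reads, the chromosome 1 copies of mitochondrial genes left out, and protein-coding genes only, the latter 2 with libraries rescaled to the remaining reads. A count test planned for deposited counts was not run, since the columns of counts were not assigned to samples by value; limma-voom took the same reads as recovered from FPKM. Enrichment of deposited annotation terms and a comparison with a deposited table of fold changes were also planned and were not run, since the files used here hold neither.

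The fit was tested on simulated reads for the same genes, with 200 genes changed by known folds and a dispersion of 0.0129 taken from the libraries. Of 50 genes per fold, 70.0% were called in the true direction at 2-fold and 100% at 4-fold, 8-fold and 16-fold. Of 16802 unchanged genes 34 were called, which made up 15.5% of the 219 calls, above the nominal 5%. Camera called the raised list and 0 of 20 unchanged lists. All genes were given the same dispersion, a median over genes, so the shares called do not hold for genes that vary more between replicates. S100a8, chosen after its values were seen, had a log2 fold change of 5.13 in the real libraries and was not called (limma adjusted p = 0.0584). The false share also depends on how many genes were changed. Reads were simulated independently for each gene, so this does not test false calls among correlated genes. The estimated correlation of the real lists reached 0.777 (intercalated cells). Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.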

Results

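Whole-kidney gene expression was compared between mice with ADPKD, an inherited disorder in which fluid-filled cysts grow from kidney tubules, and WT mice, with 2 libraries per group. Per the labels, the ADPKD model was made by giving tamoxifen to mice with a floxed Pkd1 gene, which encodes polycystin-1, and an inducible Cre recombinase. The labels give the same tamoxifen injection on postnatal day 10 for the WT samples. The reads assigned to genes numbered 18385710 in WT replicate 1, 18001308 in WT replicate 2, 18562606 in ADPKD replicate 1 and 19955120 in ADPKD replicate 2. Log2 values correlated across genes, which are not independent replicates, at 0.96 between the WT libraries, 0.94 between the ADPKD libraries and 0.86 to 0.89 between groups. Replicates differed by more than counting noise, with a chi-square per gene of 58.6 in WT and 66.2 in ADPKD.

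The libraries also differed in ways that the labels do not describe, shown here by genes chosen after their values were seen. Xist, the RNA that silences an X chromosome in females, stood at 29.6 FPKM in ADPKD replicate 2 and at 0.0121 to 0.0217 FPKM in the other 3 libraries. The Y-linked gene Ddx3y stood at 0.0482 FPKM in ADPKD replicate 2 and at 8.46 to 15.1 FPKM in the others. A cluster of 7 pseudogenes on chromosome 1 (24611535 to 24616197) resembles mitochondrial genes. It took 9.48% ± 0.0134 (half-width of the 95% Wilson interval) of the reads of WT replicate 1 and 6.11% ± 0.0111 of those of WT replicate 2. The share was 3.85% ± 0.00875 in ADPKD replicate 1 and 3.49% ± 0.00805 in ADPKD replicate 2. Of the 37 genes of the mitochondrial chromosome 0 were listed among the FPKM values, so mitochondrially encoded transcripts were not analysed here.

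Kidneys with ADPKD expressed more of the genes of tubule injury, inflammation and scarring than WT kidneys, and less of the marker genes of the proximal tubule. Camera called these lists with a preset correlation, and 0 lists with an estimated correlation. With an estimated correlation camera rests on the 2 residual degrees of freedom, so a call among 33 lists was hardly possible. The extracellular matrix list had an estimated correlation of -0.0184, below the preset 0.01, and still a camera adjusted p = 0.322. The absence of calls therefore cannot decide whether correlation between genes accounts for the lists. Of 17001 genes tested, 1604 rose and 813 fell, and of these 284 rose and 151 fell by at least 4-fold. The largest rise was that of Lcn2 (lipocalin 2, a marker of tubule injury; chromosome 2, 32384633 to 32388252), from 1.84 ± 0.0317 to 381 ± 38.1 FPKM (SD, n = 2). Its log2 fold change was 7.07 (SE 0.15, limma adjusted p = 0.00457). With all 4 libraries the largest fall apart from pseudogenes was that of Slc7a13 (an amino acid transporter of the late proximal tubule; chromosome 4, 19818725 to 19842218), from 223 ± 252 to 1.82 ± 0.147 FPKM. Its log2 fold change was -5.60 (SE 1.05, adjusted p = 0.0389). Slc7a13 stood at 44.99 and 401 FPKM in WT replicates 1 and 2, and its log2 fold change was -7.16 without WT replicate 1 and -4.03 without WT replicate 2, where that of Nccrp1 was -5.01. The Slc7a13 call was lost without ADPKD replicate 1 (adjusted p = 0.138), without ADPKD replicate 2 (0.142), with no filter (0.108) and with median-of-ratios scaling (0.0574), the robust prior (0.0654) and voom on recovered reads (0.0623).

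The complement gene C3 (chromosome 17, 57203970 to 57228136) rose from 2.31 ± 0.819 to 205 ± 30.7 FPKM. Havcr1, which encodes kidney injury molecule 1 (chromosome 11, 46735080 to 46779578), rose from 0.382 ± 0.208 to 75.0 ± 13.4 FPKM. The metalloproteinase inhibitor gene Timp1 (chromosome X, 20870166 to 20874735) rose from 0.494 ± 0.168 to 58.0 ± 3.98 FPKM, and these 3 genes shared an adjusted p = 0.00985. The fibrinogen gamma chain gene Fgg rose by 5.47 on the log2 scale (SE 0.38, adjusted p = 0.0164). S100a9, which encodes a calcium-binding protein abundant in neutrophils, rose by 5.65 (SE 1.05, adjusted p = 0.0388). It stood at 28.2 FPKM in ADPKD replicate 1 and 250 FPKM in ADPKD replicate 2. The S100a9 call was lost with voom on recovered reads (adjusted p = 0.169), the robust prior (limma adjusted p = 0.0652) and no filter (0.108). Quantile normalization (0.0546) and median-of-ratios scaling (0.0669) also lost it, as did leaving out ADPKD replicate 2 or either WT replicate. The log2 fold change of S100a9 was 7.20 without ADPKD replicate 1 and 4.09 without ADPKD replicate 2.

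Kap, an androgen-dependent gene of the proximal tubule, stood at 19114 and 34702 FPKM in WT, and at 2101 and 297 FPKM in ADPKD replicates 1 and 2. It fell by 5.02 (SE 1.01, adjusted p = 0.0439), and the lowest value belonged to the library with Xist. The Kap call was lost with the replicate block (limma adjusted p = 0.0671), the robust prior (0.0710) and no filter (0.152). Quantile normalization (0.0696) and median-of-ratios scaling (0.0554) also lost it, as did leaving out ADPKD replicate 2 or either WT replicate. The log2 fold change of Kap was -6.43 without ADPKD replicate 1 and -3.62 without ADPKD replicate 2. Egf, made by the thick ascending limb, fell by 4.84 (SE 0.34, adjusted p = 0.0164), and 9.82% of its exon length lies under exons of other genes. Nccrp1 fell by 5.13 (SE 0.17, adjusted p = 0.00985). The organic anion transporter genes Slc22a28 (log2 fold change -5.47, SE 0.47, adjusted p = 0.0177) and Slc22a30 (-4.82, SE 0.59, adjusted p = 0.0231) also fell. They belong to a family of close paralogs, and reads with several alignments were counted, so the division of reads among them is uncertain.

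**Figure D1:**
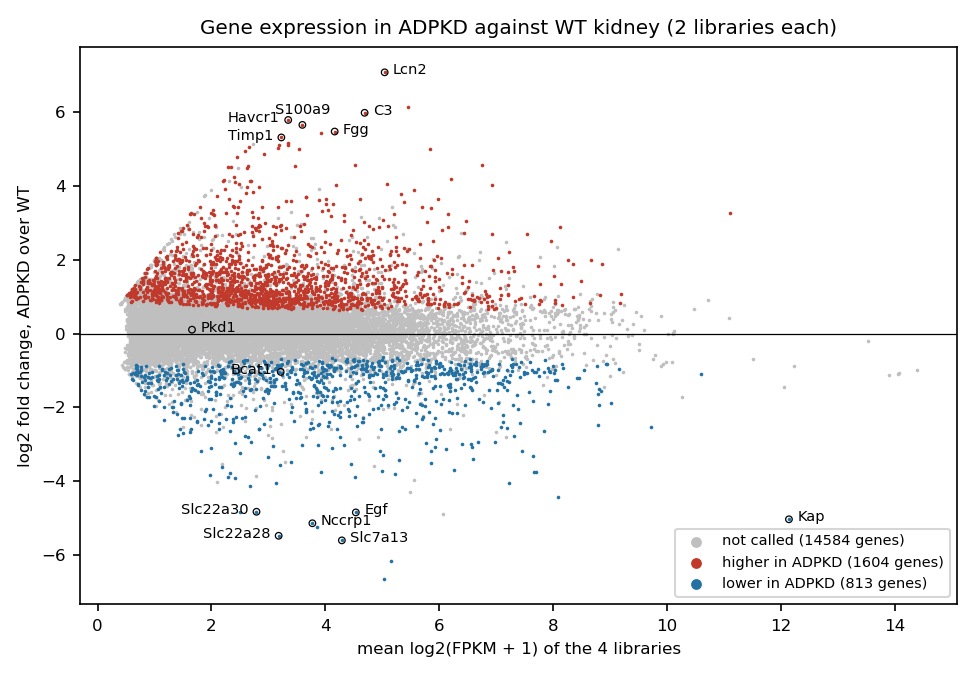
Each point is 1 of the 17001 genes tested, with the mean log2(FPKM + 1) of the 4 libraries on the x axis and the log2 fold change of ADPKD over WT on the y axis; red points rose (1604 genes), blue points fell (813 genes) and grey points were not called. Lcn2 lies at 7.07, Slc7a13 at -5.60 and Pkd1 at 0.10.

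**Figure D2:**
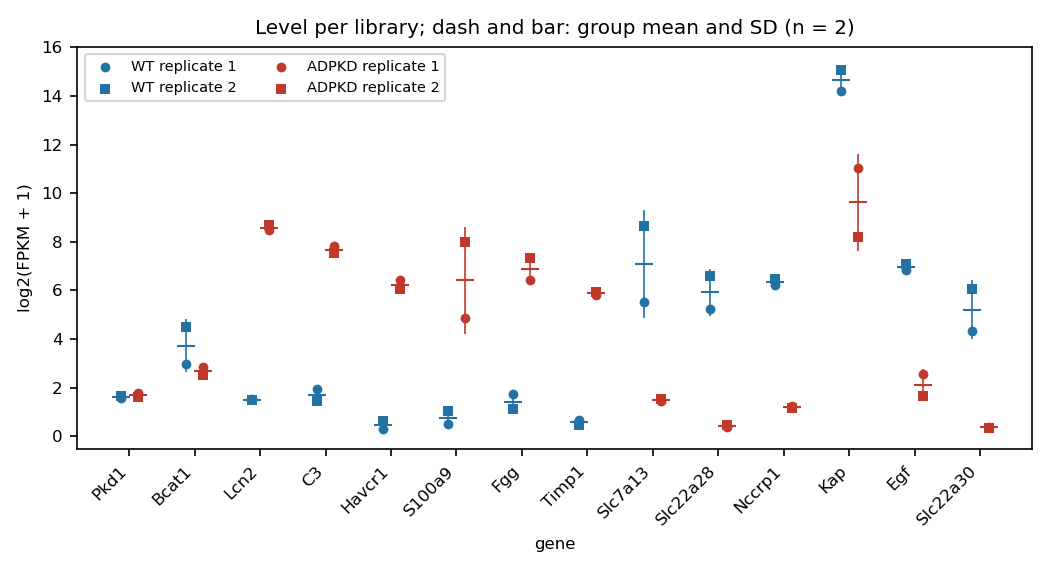
Level of Pkd1, Bcat1 and the 12 genes with the largest rises and falls, as log2(FPKM + 1) on the y axis, in each library (circles, replicate 1; squares, replicate 2; blue, WT; red, ADPKD), with the group mean as a dash and its SD as a bar (n = 2). The groups do not overlap for these 12 genes, and Bcat1 stands at 6.87 and 21.5 FPKM in the WT libraries.

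The 2417 called genes all had both ADPKD libraries on 1 side of both WT libraries. Chance gives this for a share of 0.333 of genes not selected by a test. A call with 2 against 2 libraries nearly requires it, so it adds no support. The excess of rises depended on the scaling between libraries: 66.4% of the called genes were higher in the values as deposited, 47.5% after quantile normalization and 45.7% with median-of-ratios scaling. The median log2 fold change of all genes, 0.18 in the values as deposited, was -0.0125 after quantile normalization and 0.00608 with median-of-ratios scaling. Without ADPKD replicate 1, 552 genes were called, and 574 without WT replicate 1 and 264 without WT replicate 2. Without ADPKD replicate 2 limma called 0 genes, with 5039 at an unadjusted p under 0.05, against 5878 with all 4 libraries. Of the 43 calls among the genes named by rule, those fits kept 19, 24, 19 and 0. In the 17 called lists 90 members rose and 78 fell, against 66 and 10 without ADPKD replicate 1, 50 and 18 without WT replicate 1, 38 and 7 without WT replicate 2 and 0 without ADPKD replicate 2. They numbered 81 and 65 after quantile normalization and 67 and 65 with median-of-ratios scaling.

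Whether expression of the floxed gene differed was asked of Pkd1 itself (chromosome 17, 24549834 to 24596508). Pkd1 stood at 2.04 ± 0.109 FPKM in WT and 2.28 ± 0.285 FPKM in ADPKD kidney (SD, n = 2). Its log2 fold change of 0.10 (SE 0.17, limma adjusted p = 0.703) did not pass the test, and was -0.14 after quantile normalization and -0.0552 with median-of-ratios scaling. The labels do not say which exons are removed, and a value over all exons in whole kidney does not measure a deletion of part of the gene in part of the cells.

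Genes of kidney injury and dedifferentiation rose as a group. Of 24 tested, 21 rose and 0 fell (23 and 0 adjusted over the list alone), with a median log2 fold change of 2.75 (camera adjusted p = 3.17e-13). The list had an adjusted p = 0.322 with an estimated correlation. Extracellular matrix and fibrosis genes did likewise: 25 of 30 rose (27 adjusted over the list alone), with a median of 1.98 (camera adjusted p = 1.46e-12; adjusted p = 0.322 with an estimated correlation). Mmp14, a membrane metalloproteinase gene, rose from 1.59 ± 0.0546 to 18.9 ± 0.923 FPKM (adjusted p = 0.0152). Lox, whose product crosslinks collagen, rose from 1.79 ± 0.591 to 28.8 ± 3.72 FPKM (adjusted p = 0.0164). Immediate-early genes, which include those of the AP-1 transcription factors, rose in 14 of 16 cases (16 adjusted over the list alone), with a median of 2.46. Their camera adjusted p was 1.56e-08 (adjusted p = 0.539 with an estimated correlation). The transcription factor genes Maff (3.41, SE 0.27) and Klf6 (2.87, SE 0.23) had the smallest adjusted p of that list, 0.0165 each. The largest log2 fold change in the list was 3.58.

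Inflammatory genes and leukocyte markers were also higher in ADPKD kidney. Of 23 cytokine, chemokine and innate signal genes 13 rose and 1, the chemokine gene Cxcl12, fell (18 and 2 adjusted over the list alone). The list's mean log2 fold change was 2.69 (camera adjusted p = 2.65e-05; adjusted p = 0.544 with an estimated correlation). The number that rose was 8 after quantile normalization and 7 with median-of-ratios scaling. Cxcl16, a chemokine gene with 18.3% of its exon length under exons of another gene, rose from 12.4 ± 0.947 to 54.4 ± 4.30 FPKM (adjusted p = 0.0164). Tnfrsf12a, which encodes the receptor of the cytokine TWEAK, rose by 3.02 (SE 0.23, adjusted p = 0.0164). Macrophage and monocyte markers rose in 13 of 16 cases (15 adjusted over the list alone), with a median of 2.90 (camera adjusted p = 1.40e-07; adjusted p = 0.544 with an estimated correlation). With median-of-ratios scaling 7 of them rose, and 11 after quantile normalization. Of these 16 markers 10 had a mean of at least 1 FPKM in WT kidney. Lyz2, the lysozyme gene of macrophages, stood at 9.15 ± 0.668 FPKM in WT and 330 ± 111 FPKM in ADPKD (adjusted p = 0.0152), and can share reads with its paralog Lyz1.

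Neutrophil markers had a median of 2.25, or 2.20 with the 2 genes listed at 0 in both WT libraries, Retnlg and Mmp8, set to 3 reads per library. The list was called by camera (adjusted p = 0.00270; adjusted p = 0.544 with an estimated correlation). Of its 10 members 3 rose (7 adjusted over the list alone), namely Csf3r (1.35, SE 0.19, adjusted p = 0.0278), Cxcr2 and S100a9. Of the 10 members 0 had a mean of at least 1 FPKM in WT kidney, so their WT values lie near the floor. The list had 9 tested members and a median of 3.20 without ADPKD replicate 1, and 6 and 2.74 without ADPKD replicate 2. Its median was 4.23 with a pseudocount of 0.1 and 6.28 with voom on recovered reads. With a mean of at least 5 FPKM it was 4.13 and the list was not called (adjusted p = 0.0823, in a range over all settings of 2.71e-08 to 0.544). Of T and NK cell genes 4 were tested, too few for camera, and 1 rose, Thy1 (2.26, SE 0.47, adjusted p = 0.0461). Thy1 stood at 14.8 and 5.66 FPKM in ADPKD replicates 1 and 2. Its call was lost with quantile normalization, median-of-ratios scaling and the robust prior (limma adjusted p = 0.0624, 0.0566 and 0.0520). A rise of T and NK cells is therefore not shown. Of 5 B cell and plasma cell genes 1 rose, Xbp1 (0.99, SE 0.14, adjusted p = 0.0281), which many secretory cells express. The B cell list had a median of -0.0747 and a mean of 0.0628, and was not called (camera adjusted p = 0.759); without ADPKD replicate 2 its median was 0.33.

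The series title speaks of metabolic reprogramming, and transcripts for mitochondrial pathways of energy metabolism were lower in ADPKD kidney. Nuclear genes of oxidative phosphorylation fell in 17 of 23 cases and 0 rose (21 and 0 adjusted over the list alone), with a median log2 fold change of -0.95. Their camera adjusted p was 7.07e-15 (adjusted p = 0.322 with an estimated correlation). The complex III gene Uqcrc2 fell from 124 ± 5.17 to 59.9 ± 3.32 FPKM (adjusted p = 0.0266), with 19.7% of its exon length under exons of another gene. Uqcrfs1, of the same complex, fell from 288 ± 3.48 to 140 ± 7.90 FPKM (adjusted p = 0.0281). Tricarboxylic acid cycle genes fell in 10 of 17 cases (16 adjusted over the list alone), with a median of -0.81 (camera adjusted p = 3.52e-11; adjusted p = 0.322 with an estimated correlation). Among them the succinate dehydrogenase gene Sdhb fell by 1.35 (SE 0.17, adjusted p = 0.0233) and the isocitrate dehydrogenase gene Idh3b by 1.09 (SE 0.14, adjusted p = 0.0242). Proximal tubule markers, which belong to a cell type rich in mitochondria, had a median of -1.76 in the same libraries.

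Transcripts for the breakdown of branched-chain amino acids, a mitochondrial pathway for leucine, isoleucine and valine, were lower as well. Of its 25 genes 15 fell and 0 rose (20 and 0 adjusted over the list alone), with a median log2 fold change of -0.88 (camera adjusted p = 7.07e-15; adjusted p = 0.322 with an estimated correlation). The propionyl-CoA carboxylase gene Pcca fell from 24.9 ± 0.367 to 8.58 ± 0.735 FPKM (adjusted p = 0.0199). The methylmalonyl-CoA epimerase gene Mcee fell from 82.6 ± 0.584 to 35.8 ± 2.18 FPKM (adjusted p = 0.0226). Bcat1, the cytosolic transaminase gene of these amino acids (chromosome 6, 144993835 to 145076184), did not pass the test (log2 fold change -1.04, SE 0.53, adjusted p = 0.244). It stood at 6.87 and 21.5 FPKM in WT replicates 1 and 2, and at 6.28 and 4.78 FPKM in the ADPKD libraries. Its log2 fold change was -0.28 without WT replicate 2 (adjusted p = 0.655) and -1.79 without WT replicate 1 (adjusted p = 0.0503).

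Gluconeogenesis and fatty acid oxidation genes were lower as lists, with few called members, beside proximal tubule markers with a median of -1.76. Of 8 gluconeogenesis genes 4 fell, among them Pcx and Fbp1 (2 rose and 4 fell adjusted over the list alone). The list's median was -0.87 (camera adjusted p = 0.00572; adjusted p = 0.544 with an estimated correlation). With median-of-ratios scaling 1 of the 8 fell, and 3 after quantile normalization. Pyruvate carboxylase, Pcx, fell by 1.44 (SE 0.15, adjusted p = 0.0204) and fructose bisphosphatase, Fbp1, by 1.55 (SE 0.24, adjusted p = 0.0302). Without ADPKD replicate 1 its median was -0.53 and the list was not called (adjusted p = 0.0665, in a range over all settings of 0.000329 to 0.544). Of 25 fatty acid oxidation genes 3 fell (3 adjusted over the list alone), with a median of -0.48 (camera adjusted p = 1.27e-05; adjusted p = 0.587 with an estimated correlation). Its median was -0.23 without WT replicate 2. The genes that fell were Hadh and the medium-chain acyl-CoA synthetase genes Acsm2 (-3.07, SE 0.38, adjusted p = 0.0237) and Acsm1 (-1.78, SE 0.23, adjusted p = 0.0248).

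Glycolysis genes went both ways, and the list was not called (camera adjusted p = 0.770). Of 17 members Slc16a3, Pfkp, Slc2a1 and Hk2 rose and Pfkm fell (5 rose and 2 fell adjusted over the list alone). The lactate transporter gene Slc16a3 rose by 1.499 (SE 0.20, adjusted p = 0.0254) and the phosphofructokinase gene Pfkp by 1.14 (SE 0.17, adjusted p = 0.0289). With median-of-ratios scaling 2 of the 17 rose. The list's median was 0.0757 and its mean 0.26, while camera pointed down, and the median was -0.15 with median-of-ratios scaling. Of 18 genes of amino acid and glutamine uptake and use 5 rose, among them Asns and Slc7a5 (9 rose and 3 fell adjusted over the list alone), and 3 rose with median-of-ratios scaling. Asparagine synthetase, Asns, rose by 2.26 (SE 0.23, adjusted p = 0.0201) and the amino acid transporter gene Slc7a5 by 1.601 (SE 0.20, adjusted p = 0.0239). That list had a median of 0.80 and was not called (camera adjusted p = 0.308).

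**Figure D3:**
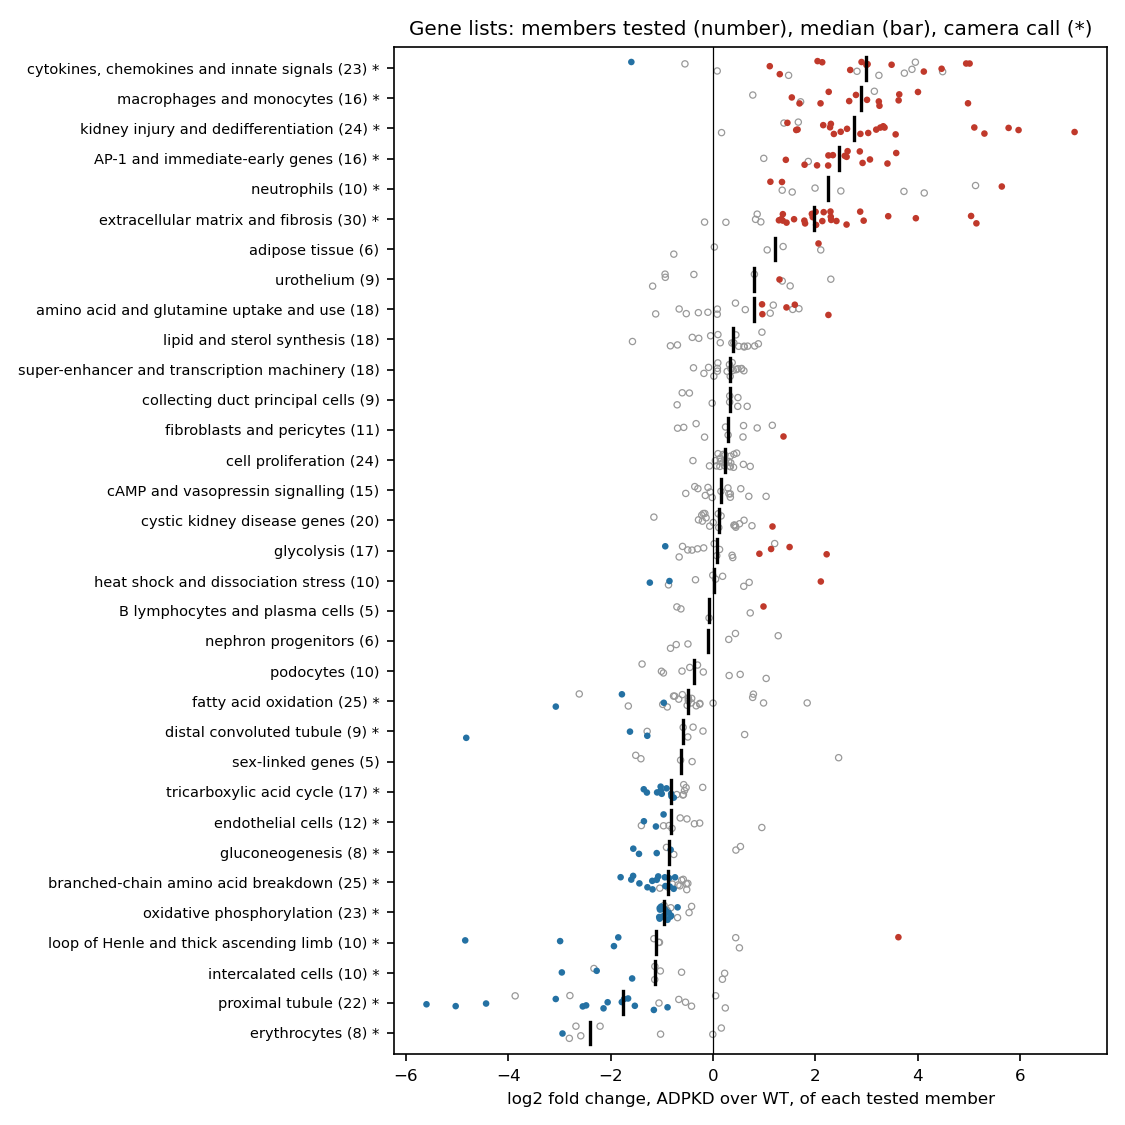
Log2 fold change of ADPKD over WT (x axis) of each tested member of the 33 lists tested with camera (y axis, number of members in brackets), with red points for members that rose, blue points for members that fell, open grey points for members not called, a black bar for the list's median and a star for a camera call. The median is 2.75 for kidney injury and -1.76 for proximal tubule; 17 lists were called with the preset correlation, 0 with an estimated correlation and 7 by fry.

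Markers of several nephron segments and of the endothelium were lower in ADPKD kidney, and those of collecting duct principal cells were not called. Proximal tubule markers fell in 14 of 22 cases (16 adjusted over the list alone), with a median log2 fold change of -1.76 (camera adjusted p = 1.94e-11; adjusted p = 0.322 with an estimated correlation). With quantile normalization 7 of the 22 fell, and 11 with median-of-ratios scaling. The scaffold protein gene Pdzk1 fell from 123 ± 15.2 to 35.3 ± 5.65 FPKM (adjusted p = 0.0206), although 41.7% of its exon length lies under exons of other genes, so its reads are uncertain. Of 10 markers of the loop of Henle and thick ascending limb Egf, Ppp1r1a, Cldn10 and Slc12a1 fell and Bst1 rose (7 fell and 1 rose adjusted over the list alone). Their median was -1.11 (camera adjusted p = 0.00274; adjusted p = 0.544 with an estimated correlation). Of 9 distal convoluted tubule markers 3 fell, Pvalb, Slc12a3 and Klhl3 (3 adjusted over the list alone), with a median of -0.58 (camera adjusted p = 0.000150; adjusted p = 0.322 with an estimated correlation). That median was -1.01 without WT replicate 2 and -0.93 with a mean of at least 5 FPKM. Parvalbumin, Pvalb, stood at 25.9 and 32.9 FPKM in WT and at 0.144 FPKM in ADPKD replicate 2 (adjusted p = 0.00985). It was listed at 0 in ADPKD replicate 1, where 3 reads would be 0.155 FPKM.

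Of 10 intercalated cell markers Slc4a1, Rhbg and Insrr fell (6 adjusted over the list alone), with a median of -1.13 (camera adjusted p = 8.73e-05; adjusted p = 0.544 with an estimated correlation). Without ADPKD replicate 2 that median was -0.68. The anion exchanger gene Slc4a1 fell by 2.95 (SE 0.16, adjusted p = 0.0152). Of 12 endothelial markers Tek, Tie1 and Egfl7 fell (4 adjusted over the list alone), with a median of -0.83 (camera adjusted p = 3.01e-05; adjusted p = 0.544 with an estimated correlation). The angiopoietin receptor gene Tek fell by 1.35 (SE 0.15, adjusted p = 0.0218). Collecting duct principal cell markers had a median of 0.33 and a mean of 0.0592, while camera pointed down (adjusted p = 0.912). Limma called 0 of 9 (0 adjusted over the list alone), with 3 at an unadjusted p under 0.05. The sodium channel gene Scnn1b stood at 28.7 ± 0.826 FPKM in WT and 46.5 ± 7.16 FPKM in ADPKD (adjusted p = 0.0688).

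Podocyte markers had a median of -0.38 (camera adjusted p = 0.0689), and limma called 0 of 10 (0 adjusted over the list alone), with 4 at an unadjusted p under 0.05. The median was -0.20 without ADPKD replicate 1 and -0.71 without ADPKD replicate 2. The cell cycle inhibitor gene Cdkn1c had the smallest adjusted p (0.0683), with 30.7% of its exon length under exons of another gene. Camera called the podocyte list lower without ADPKD replicate 2 (adjusted p = 0.00128) and with voom on recovered reads (adjusted p = 0.0476), in a range over all settings to 0.720. Fibroblast and pericyte markers were not called as a list (median 0.30, camera adjusted p = 0.912), and 1 of 11, the matrix proteoglycan gene Dcn, rose by 1.36 (SE 0.16, adjusted p = 0.0224). The fibroblast median was 0.72 without ADPKD replicate 1. Nephron progenitor markers were not called (median -0.0885, camera adjusted p = 0.381). Limma called 0 of these 6 markers, with 1 at an unadjusted p under 0.05, Lhx1 (-0.83, adjusted p = 0.0612). Of 9 urothelial markers 1 rose, Upk3b (1.29, SE 0.24, adjusted p = 0.0399), whose call was lost with the replicate block (limma adjusted p = 0.0636). That list had a median of 0.81 while camera pointed down (adjusted p = 0.949), and its median was -1.66 without ADPKD replicate 1 (adjusted p = 0.0349, in a range over all settings to 0.999). In that library the basal keratin gene Krt5, chosen after its values were seen, stood at 49.9 FPKM, against 1.09 to 3.54 FPKM in the other 3.

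Lists on other themes of cystic disease did not pass the test. Of 20 cystic kidney disease genes 1 rose, Bicc1 (1.15, SE 0.22, adjusted p = 0.0410), which encodes an RNA-binding protein, and 0 passed when adjusted over the list alone. The list's median was 0.11 (camera adjusted p = 0.997), and -0.13 after quantile normalization and -0.0440 with median-of-ratios scaling. Pkhd1, the gene of the recessive form, stood at 7.82 ± 0.190 FPKM in WT and 12.5 ± 1.02 FPKM in ADPKD (adjusted p = 0.0648). Limma called 0 of 24 cell proliferation genes (0 adjusted over the list alone), with 2 at an unadjusted p under 0.05 (median 0.24, camera adjusted p = 0.582). The median was 0.0234 without ADPKD replicate 1, 0.405 without ADPKD replicate 2, 0.402 without WT replicate 1 and 0.0635 without WT replicate 2. The 2 genes were Rrm2, for nucleotide synthesis (0.73, adjusted p = 0.114), and Mcm3, for DNA replication (0.60, adjusted p = 0.144). Of 18 genes of super-enhancers and the transcription machinery 0 were called by limma (0 adjusted over the list alone), with 4 at an unadjusted p under 0.05 (median 0.33, camera adjusted p = 0.381). The kinase gene Cdk9 stood at 0.56 (adjusted p = 0.0716) and the bromodomain gene Brd2 at 0.49 (adjusted p = 0.114).

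Genes of cAMP and vasopressin signalling had a median of 0.16, while camera pointed down (adjusted p = 0.970), and the median was -0.0652 with median-of-ratios scaling. Limma called 0 of 15 (0 adjusted over the list alone), with 1 at an unadjusted p under 0.05, the chloride channel gene Cftr (1.04, adjusted p = 0.0641). The phosphodiesterase gene Pde3a stood at 0.55 (adjusted p = 0.163). Lipid and sterol synthesis genes had a median of 0.39 (camera adjusted p = 0.997), and limma called 0 of 18 (0 adjusted over the list alone), with 4 at an unadjusted p under 0.05. The median was 0.101 without ADPKD replicate 1 and 0.0705 without WT replicate 2. Among the 4 genes the sterol regulator gene Srebf2 stood at 0.61 (adjusted p = 0.0667).

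Of the lists for sample quality, camera called that of erythrocyte genes. It had a median log2 fold change of -2.39 (camera adjusted p = 0.00138; adjusted p = 0.544 with an estimated correlation), but the 1 of 8 that fell (1 adjusted over the list alone) was Slc4a1, which intercalated cells also express. Without WT replicate 1 the median was -1.49. The globin gene Hba-a1, chosen after its values were seen, stood at 692 and 151 FPKM in WT replicates 1 and 2, and at 71.5 and 34.6 FPKM in the ADPKD libraries (adjusted p = 0.0974). Of 10 heat shock and dissociation stress genes Hspb1 rose and Hspe1 and Hspd1 fell (2 rose and 2 fell adjusted over the list alone). That list had a median of 0.0257 while camera pointed down (adjusted p = 0.450), and the median was -0.0897 after quantile normalization and -0.20 with median-of-ratios scaling. Of 6 adipose tissue genes 1 rose, Plin4 (median 1.22, camera adjusted p = 0.582). Adipsin, Cfd, chosen after its values were seen, stood at 38.6 FPKM in ADPKD replicate 1 and at 0.0544 to 1.12 FPKM in the other 3 libraries. Of adrenal cortex genes 2 were tested, too few for camera, and 1 fell, Hsd3b6 (adjusted p = 0.0321). The 5 sex-linked genes were not called as a list (median -0.63, camera adjusted p = 0.347), and limma called 0 of them, with 0 at an unadjusted p under 0.05. Without ADPKD replicate 1 that list had a median of -1.48 and was called (adjusted p = 0.0212, in a range over all settings to 0.713).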

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

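Apart from 3 settings chosen after seeing the data (voom, the chromosome 1 copies left out, protein-coding genes only), the settings were planned, and the cause was not tested unless stated. The 2417 calls (1604 higher, 813 lower) became 1 (1 and 0) with no filter, where more genes were tested (7251 at an unadjusted p under 0.05 by limma). At adjusted p below 0.10 there were 4471 (3038 and 1433). After quantile normalization 999 were higher, and 740 with median-of-ratios scaling. Leaving out 1 library, which leaves a lone sample assumed to vary like the other group, gave 0 to 574 calls, 0 to 435 higher and 0 to 250 lower. The labels do not say that the replicate numbers pair the samples. By value, replicate 1 matched the count columns WT2 and PKD1, and replicate 2 matched WT4 and PKD3, so equal replicate numbers need not mark pairs. Within-group differences correlated at 0.19 across genes, which with only 2 pairs cannot decide whether the samples are paired. With the replicate block 1845 genes were called. Of 17 called lists 0 were called with an estimated correlation and 7 by fry. The 16 refits kept them all, except neutrophils (mean FPKM of at least 5) and gluconeogenesis (without ADPKD replicate 1). Podocytes were called in addition with voom and without ADPKD replicate 2, and sex-linked genes and urothelium without ADPKD replicate 1. Pkd1 turned to -0.141 after quantile normalization and -0.0552 with median-of-ratios scaling. Medians of uncalled lists also changed sign: with quantile normalization, cystic genes -0.127 and heat shock -0.0897; with median-of-ratios scaling, cystic genes -0.0440, glycolysis -0.154, cAMP -0.0652 and heat shock -0.198; with no filter, nephron progenitors 0.0110. Without the chromosome 1 mitochondrial copies nephron progenitors had 0.151 and heat shock -0.0355, and with protein-coding genes only 0.163 and -0.0235. With 1 library left out, medians ran from -0.191 to 0.269 for nephron progenitors, -0.163 to 0.199 for heat shock, -1.66 to 1.17 for urothelium and -0.609 to 0.332 for B cells. With 1 library left out other uncalled medians moved over 1.5 times: without ADPKD replicate 1, cystic genes 0.00835, cAMP 0.0612, glycolysis 0.0436, principal cells 0.172 and super-enhancers 0.203; without ADPKD replicate 2, cystic genes 0.232 and cAMP 0.291. Without WT replicate 1 cAMP had 0.268 and urothelium 0.333, and without WT replicate 2 cystic genes 0.175, principal cells 0.170 and glycolysis 0.0466. Over the 16 refits, where the list could be tested, medians ran from -0.127 (quantile normalization) to 0.417 (mean FPKM of at least 5) for cystic genes, 0.264 (mean FPKM of at least 5) to 1.09 (voom) for amino acid uptake, 0.0753 (quantile normalization) to 0.392 (voom) for super-enhancers, 0.0270 (quantile normalization) to 0.719 for fibroblasts, 0.414 (no filter) to 2.59 (voom) for adipose tissue and -3.55 (voom) to -0.572 for sex-linked genes. With quantile normalization proliferation had 0.0431, lipid synthesis 0.176, cAMP 0.0314, glycolysis 0.0230, principal cells 0.184 and podocytes -0.616. With median-of-ratios scaling proliferation had 0.0914, super-enhancers 0.143, lipid synthesis 0.178, principal cells 0.104 and fibroblasts 0.108. B cells had -0.750 and nephron progenitors -0.317 with voom. Of the 2417 calls quantile normalization kept 1730, the replicate block 1629 and voom on recovered reads (3039 called) 2264, and median-of-ratios scaling (1618 called) kept 1430 of 2416. Of 43 calls among genes named by rule these lost 6, 2, 2 and 9, and the robust prior lost 4. S100a9, Kap, Bicc1, Pfkp, Thy1 and Upk3b were lost under both scalings, and Slc7a13, Fbp1 and Xbp1 with median-of-ratios scaling. Not run were the count tools and the alternatives for annotation terms and a deposited comparison. Depth limits low genes, since 1 read on 1 kb is worth 0.0501 to 0.0556 FPKM.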

Other observations

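The gene families below, defined by symbol stem, were tested after the data were seen. So were all explanations that follow except that of pseudogenes mirroring their parent genes, and the tests on proximal tubule markers replaced first forms whose results had been seen. Of 207 families of protein-coding genes with at least 8 tested members, camera called 31 (12 higher, 19 lower). With an estimated correlation, which leaves camera 2 residual degrees of freedom, 0 were called. The families named here then had a camera adjusted p = 0.974, or 0.979 for Rpl and Hoxb. Organic ion transporter genes of the Slc22a family fell in 13 of 21 cases (median log2 fold change -2.20, camera adjusted p = 5.18e-10), and 4 of these 21 are also in the lists above. Kallikrein genes of the Klk1b family fell in 7 of 10 cases (median -2.25, adjusted p = 6.30e-08). Members of both families are close paralogs that can share reads.

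Genes of mitochondrial ribosomes were lower as families: 2 of 48 Mrpl genes fell (median -0.46, adjusted p = 1.88e-09) and 4 of 29 Mrps genes (median -0.43, adjusted p = 1.52e-06). Genes of cytosolic ribosomes were higher, with 5 of 31 Rps genes (median 0.63, adjusted p = 0.00129) and 5 of 44 Rpl genes (median 0.48, adjusted p = 0.00131) rising. With median-of-ratios scaling these 2 medians were 0.40 and 0.25. Many Rps and Rpl genes have pseudogenes named for them that can share their reads, so the division of reads is uncertain. Annexin genes rose in 6 of 10 cases (median 1.003, adjusted p = 0.00176). Hoxb genes, which pattern the embryo, rose in 4 of 8 cases (median 0.73, adjusted p = 0.0198). The Hoxb call was lost without ADPKD replicate 1 (adjusted p = 0.0568) and with a mean FPKM of at least 5 (adjusted p = 0.0682), in a range over the refits from 0.000757. None of the family medians named here changed sign under either other scaling.

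The sex of the animals may differ between the libraries, since ADPKD replicate 2 alone had Xist and nearly lacked Ddx3y. ADPKD replicate 1 lacks Xist, as both WT libraries do. In the fit without ADPKD replicate 2, 17 of the 17 called lists kept their direction and camera call. The median was 2.69 for kidney injury and -1.60 for proximal tubule. This argues against sex as the whole account of these lists. That fit rests, however, on 1 ADPKD library, which also helped to call the lists, and on the preset correlation. In that fit limma called 0 single genes (5039 at an unadjusted p under 0.05). How far sex adds to the size of single changes stays open. Acsm3, chosen after its values were seen, also differed between the WT libraries, which both lack Xist, at 0.474 and 38.1 FPKM.

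The lower proximal tubule markers may come from fewer such cells, less expression per cell, or dilution by other cells. Dilution of all resident cells by leukocytes would lower every resident type alike, which is argued against by a proximal tubule median -1.13 from that of the 60 members of 6 other resident lists (loop of Henle, distal tubule, principal cells, intercalated cells, podocytes and endothelium; permutation p = 0.000230, 100000 permutations over genes, which are not independent). A lower share of proximal tubule cells alone would raise the other types. This is argued against by the median of those 60 members, -0.625, with 45 of 60 lower. Its 95% interval, -0.965 to -0.455, came from 10000 resamplings of members within lists. That interval takes genes as independent, which they are not, and does not measure variation between animals. With fibroblasts and pericytes added, which were not among the 6, the median was -0.569 over 71 members (-0.698 to -0.300). Camera called 4 of the 6 lists lower (0 with an estimated correlation). The medians of principal cells and of fibroblasts and pericytes lay above 0 in each of the 16 refits (0.104 to 0.338 and 0.0270 to 0.719). Neither of these lists was called, camera pointed down for principal cells, and the median of all genes was 0.18. A difference in direction between the types is therefore not shown. A lower share together with dilution stays open, and lower expression per cell was not tested.

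Some of the largest fold changes belonged to processed pseudogenes, such as Rpl10-ps5 (log2 fold change 4.55, adjusted p = 0.0152) beside its parent Rpl10 (0.56, adjusted p = 0.0831), both chosen after their values were seen. A candidate explanation is that reads are placed differently among near-identical copies in different libraries. Of 771 processed pseudogenes 9.60% differed over 4-fold between the WT libraries, against 0.371% of protein-coding genes matched on reads, and 8.82% against 0.864% between the ADPKD libraries, ratios of 25.9 and 10.2. These gaps lie within groups, whereas the groups do not overlap for any called gene. They show that values of processed pseudogenes vary more between replicates, and cannot decide what caused the called changes between groups. Whether pseudogenes mirror their parents stays open, since across 327 pairs the fold changes correlated at 0.492, between the limits of 0.2 and 0.5 set against and for it. No biological explanation was tested.

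Near the floxed locus, 41 of the 335 tested genes within 10 Mb of Pkd1 were called, 12.2%, against 14.3% elsewhere (Fisher's exact test, two-sided p = 0.343). Between the ADPKD libraries, the neutrophil gene Ngp stood at 33.9 FPKM in replicate 2 and was listed at 0 in replicate 1, where 3 reads would be 0.132 FPKM. Saa3, an acute phase gene, stood at 93.6 FPKM in replicate 2 and 0.930 FPKM in replicate 1. These 2 genes were chosen after their values were seen.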
